A study of Rattus norvegicus with 6 samples.

How the data were processed

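Total RNA from 6 rat testes was labelled with Cy3 as cRNA from 1 ug per sample and hybridised to one-colour Agilent arrays, per the labels' protocols. Each array was read with Agilent Feature Extraction, per the submitters' processing notes, at version 11.0.1.1 per the file headers. The deposited scanner files give for each spot an intensity after background subtraction (the processed signal), the median intensity of the spot and of its local background, and flags (other values, 0 or 1, per the file headers) for outlier, saturated and well-above-background spots. The authors' value table holds 1 deposited log2 value per probe and array. Its method is not given in the sources used here. Set against the log2 processed signal of the same array over 39841 probes, its columns correlated at r = 0.992 to 0.999 with slopes of 0.94 to 1.07, and each of the 6 columns had a median of 4.42, a 75th percentile of 6.05 and a maximum of 17.73, as quantile normalization would leave them. Sorted values differed by at most 0.58 from those of the first column. Its scale is taken as log2, and it was used only as an alternative.

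Samples were grouped by their titles, as 3 control and 3 DEHP arrays from 3 rats each, per the labels. Control spots and spots flagged as outliers (65 to 86 per array) were left out. No spot was saturated. Log2 processed signals were averaged over the spots of a probe (1 spot per piRNA probe, 10 per other probe). Over replicated spots of a probe the SD was 0.07 to 0.10 log2 units per array, and the median signal of the negative control spots was 3.70. Each array was centred on its 75th percentile over all probes apart from controls, since the mean share of probes well above background was 55.1%, above the 50% set for this choice. Probes were kept if they were well above background on at least 3 of the 6 arrays, without regard to group, and had a value on every array, which left 23090 of 39886. The number of arrays limits the precision of every value.

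The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the 23090 probes and a threshold of 0.05. All adjusted p-values of single probes are limma's and two-sided. Probe classes were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry, adjusted over 3 classes. Single values per array were compared with two-sided exact permutation tests, for which 3 against 3 arrays allow no p under 0.1. A probe well above background on all arrays of one group and none of the other was given a bound: the mean of the bright group against the mean, in the dim group, of the higher of the lowest detected signal of the array and the probe's own signal. The method was tested on simulated data for the comparison of DEHP with control: over 5 rounds with 200 of 23090 probes changed, 4.18% of 1.5-fold, 45.4% of 2-fold and 91.2% of 4-fold changes were recovered, and 4.89% of calls were false. The simulated noise was independent between probes and held no slide, array or intensity effect. The simulated rates therefore do not carry over to the calls made on the real arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

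The groups, tests, gene lists, most alternatives and the rule for named probes were chosen before the data were examined. The rule took the 12 largest increases and the 12 largest decreases among probes that passed, were well above background on all 6 arrays and had no overlap between groups, with the 3 largest bounds in each direction, the 5 probes of highest mean signal and any gene of the fixed lists that passed. Lhcgr is reported as the only listed gene with an assigned probe. Alternatives were quantile normalization, no centring, the 75th percentile over probes detected on all 6 arrays, median centring, normexp background correction with an offset of 50 followed by quantile normalization or percentile centring, no filter, a filter at all 6 arrays, the authors' value table, the replicate number as a block, the slide as a block, eBayes without trend or robust, array weights, and each array left out in turn. Cyclic loess, the arrays of slide 1 alone, the slide in the class tests, other scalings in the class tests and arrays left out of the detection counts were added after the data were seen. Slides were told apart by the scan identifier in the file headers, which is assumed to mark a slide.

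Some planned steps were changed. Normexp was planned on the mean spot signal and was run on the median spot signal, the one read here. Classes of piRNAs by length, first base, genomic context, chromosome or cluster were not analysed here, since they need sequences or positions. Gene symbols were assigned by RefSeq accession from a table of the GRCr8 assembly, which matched 61 of 67 mRNA probes to 38 genes. Different probes of a gene were kept apart.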

Results

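Probes for PIWI-interacting RNAs (piRNAs), small germline RNAs that guide PIWI proteins, were read in the testis of male Sprague-Dawley rats on 6 one-colour Agilent arrays. DEHP, di(2-ethylhexyl) phthalate, is a plasticizer. Per the labels, 3 rats received corn oil and 3 received DEHP at 1000 mg/kg/day by gavage for 28 days, and 1 testis of each rat was used, at an age of 11 weeks. The comparison asks which piRNA probes differ in signal between DEHP-treated and control testis. The groups follow the title and the treatment label of each sample. The series' design text names the 2 treatments in the reverse order to the 2 groups, so every direction given here rests on the sample labels and would turn if the groups were exchanged. The names of the deposited files carry group marks whose meaning is not given in the sources used here, and they were not used. The array carries 39886 probes apart from controls. Of these, 39727 are named by a piRNA identifier and have 1 spot each, 67 are named by an mRNA accession, 38 by a microRNA and 54 by other identifiers. The files used here give neither the sequence nor the genomic position of a piRNA, so piRNAs are named by identifier only. Per the labels' protocol the RNA was labelled as cRNA with a Quick Amp kit. Whether the signal of a piRNA probe comes from the short piRNA or from a longer RNA with its sequence is not given in the sources used here, and a change in a piRNA below is a change in the signal of its probe.

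The number of probes well above background was 16821, 23829 and 21395 on the control arrays and 22341, 23603 and 23874 on the DEHP arrays. The group means were 20682 ± 3558 and 23273 ± 818 probes (SD, n = 3), a difference of 2591 (two-sided exact permutation test, p = 0.3, where 3 against 3 allows no p under 0.1). Without control 1, the array with the lowest count, the difference was 661, and without control 2 it was 4165. Before any centring, the 75th percentile of the log2 signal was 6.00 ± 0.33 in controls and 6.25 ± 0.12 in DEHP testis, a difference of 0.25 (SD, n = 3, exact permutation p = 0.3). That difference was 0.12 without control 1 and 0.44 without control 2. No overall change in signal was therefore detectable with 3 arrays per group. Arrays correlated across kept probes at r = 0.988 to 0.992 within the DEHP group, 0.976 to 0.985 within controls and 0.962 to 0.982 between the groups; probes are not independent replicates. The first principal component held 52.0% of the variance and separated the 3 DEHP arrays from the 3 control arrays, and the second, with 24.3%, set control 2 apart. By the scan identifier in the file headers, control 1 lay on the same slide as the 3 DEHP arrays, and controls 2 and 3 on the other. No label gives the slide, so that every value by slide rests on this reading of the identifier. Control 1 correlated with DEHP 1, DEHP 2 and DEHP 3 on its slide at 0.978, 0.975 and 0.982. Between-group pairs across slides had 0.962 to 0.974, all lower. Control 1 was closer to DEHP 1 and DEHP 3 than to control 2 (0.976), but closest to control 3 on the other slide (0.985).

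Signals of single piRNA probes that passed fell by up to 7.81-fold in DEHP testis, of 22988 piRNA probes tested. The largest nominal rise was 5.61-fold, that of DQ613172. This probe was well above background on no control array, so its rise has only a bound, of at least 1.46-fold. The probes named next were chosen among those that passed, were well above background on all 6 arrays and had no overlap between the groups. This leaves out dimmer probes, some with larger nominal increases over control signals that were not well above background. It also leaves out passing probes with nominal decreases as large as those named. DQ740242, from -1.43 in controls to -4.38 in DEHP testis, was well above background on no DEHP array. The largest decrease was that of DQ760787, from 3.12 ± 0.78 to 0.15 ± 1.16 (SD, n = 3) on the log2 scale relative to each array's 75th percentile, a change of -2.97 with a standard error of 0.53 (limma, adjusted p = 0.0137). DQ765261 changed by -2.76 and DQ614103 by -2.55. DQ732490 changed by -2.38 with a standard error of 0.19 (adjusted p = 0.00325), and DQ727441 by -2.32 with a standard error of 0.20 and the same adjusted p. DQ763258, DQ754191, DQ750488, DQ756239, DQ736962, DQ733457 and DQ737440 completed the 12 largest decreases among these probes, the least of them -2.10. The 12 largest increases among these probes were smaller. DQ625003 rose by 1.60 with a standard error of 0.35, from 2.70 ± 0.50 to 4.30 ± 0.71 (SD, n = 3, adjusted p = 0.0243). DQ760294, DQ758000, DQ743578 and DQ612411 rose by 1.47 to 1.54. DQ623665 and DQ755274 both rose by 1.43, DQ617979 by 1.24 (adjusted p = 0.0048), DQ734643 by 1.24, DQ738989 by 1.20 and DQ766201 by 1.19. The last of the 12, A_44_P621980, is not a piRNA probe and rose by 1.18. In each of these 24 probes the 3 DEHP values lay on one side of the 3 control values, since the selection required it. With the slide as a block, 1 of the 24, DQ727441, passed the test. With normexp and percentile centring the increases ranged from 0.41 to 1.62, with 11 of 12 passing, and the decreases from -2.16 to -0.99, with all 12 passing. Within slide 1 the decreases ranged from -3.13 to -1.46 and the increases from 0.76 to 1.30, and 5 of the 12 increases and all 12 decreases passed, with the lone control assumed to vary like the DEHP arrays. Of the 12 increases, 5 passed without control 3, 5 without DEHP 2, 6 without DEHP 3 and 10 without DEHP 1, and the 5 largest failed in the first 3 of these. Of the 12 decreases, 9 passed without control 3, 8 without DEHP 2, 10 without DEHP 3, 10 without DEHP 1 and 11 without control 1.

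**Figure D1:**
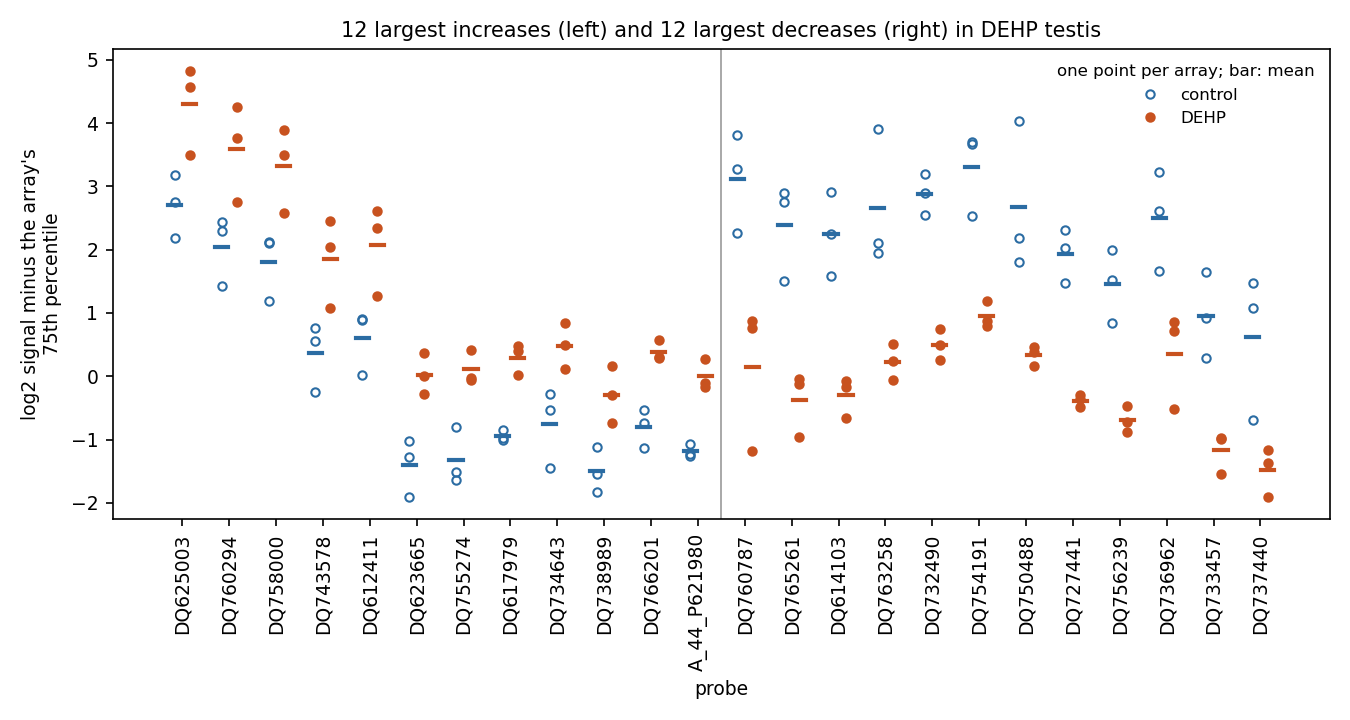
Log2 signal relative to the 75th percentile of its array (vertical axis) for the 24 probes with the largest changes (horizontal axis), with 1 point per array, open for control and filled for DEHP, and a bar at the mean of 3 arrays. No DEHP point overlaps the control points of the same probe, since the selection required it. DQ760787 changed by -2.97 and DQ625003 by 1.60.

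Over all classes, 2471 of 23090 probes (10.7%) differed at an adjusted p below 0.05, with 1026 higher and 1445 lower in DEHP testis. Among piRNA probes 992 were higher and 1439 lower. A change of at least 2-fold was seen in 171 of the higher and 391 of the lower probes. Some of the 171 were well above background on no control array, so their fold has only a bound. At an unadjusted p below 0.05, 3993 probes were higher and 3381 lower, and 672 of these changed at least 2-fold. Of the 672, 253 were higher and 419 lower. With only probes detected on all 6 arrays these counts were 44 and 380. The 3 values of each group did not overlap in 37.5% of probes, where chance gives 10% for a single probe. Probes of an array vary together, so the share over all probes can depart from 10% without a treatment difference. The comparison is no test. The split between higher and lower calls depended on how arrays were centred: 41.5% of calls were higher in the setting used here, 68.6% of 3644 calls with the 75th percentile taken over probes detected on all 6 arrays, 9.50% of 3138 calls with median centring, 55.6% of 568 calls without centring and 31.3% of 1598 calls with normexp background correction. With only probes detected on all 6 arrays it was 30.6% of 2165. The median change of all probes moved from 0.05 to 0.19, -0.15 and 0.31 in the first 3 of these alternatives, and changes are relative to it. With the slide as a block 7 probes passed, all of them lower, and 4091 had an unadjusted p below 0.05; within slide 1, where the 1 control array is assumed to vary like the DEHP arrays and any peculiarity of it counts as a group difference, 2037 passed. All 2471 probes kept their sign with the block, where the difference rests on control 1 against the DEHP arrays. Control 1 was among the arrays that selected these probes, so the kept sign was largely set in advance and tests no slide effect. Their median absolute change went from 0.76 to 0.69 and their median standard error from 0.17 to 0.22. The count was 4514 without control 2, 544 without control 3, 478 without DEHP 1, 275 without DEHP 2 and 676 without DEHP 3.

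The change of a piRNA went with its signal level, to an extent that depended on the normalization and, for dim probes, on the filter. In the lowest of 10 bins of piRNA probes by mean signal the median change was 0.40, with 153 probes higher and 9 lower. Of its 2299 probes, 1847 were detected on more DEHP than control arrays and none on all 6, so the filter at 3 of 6 arrays bears on this value. In the lowest of 10 bins made, after the data were seen, from the 16529 piRNA probes detected on all 6 arrays the median was 0.05, with 40 higher and 49 lower, and in the highest -0.29. The median of 0.40 was 0.13 after quantile normalization, 0.05 after cyclic loess, 0.03 after normexp with quantile normalization and 0.0007 after normexp with percentile centring. In the highest bin the median change was -0.27, 74.1% of probes had a negative change, and 446 were lower against 11 higher. These counts were 269 and 210 after quantile normalization, 283 and 194 after cyclic loess, 266 and 218 in the authors' value table and 156 and 66 without centring. With the slide as a block no probe of this bin passed, with a median of -0.31. The mean of the highest bin, relative to all piRNA probes of the same array, was 4.98 ± 0.20 in controls and 4.64 ± 0.08 in DEHP testis (SD, n = 3), a difference of -0.34 (exact permutation p = 0.1, the smallest 3 against 3 allows). The median change of the highest bin was 0.03 after quantile normalization, 0.02 after normexp with quantile normalization, 0.03 in the authors' value table and 0.01 after cyclic loess. Quantile normalization gives every array the same distribution, cyclic loess removes a trend of change on level, and the authors' columns share 1 median, 75th percentile and maximum. A value near 0 follows from these properties and does not test the direction. Centring moves all bins alike and leaves the gap between them: without it the medians of the lowest and the highest bin were 0.65 and -0.02. With normexp and percentile centring the highest bin had -0.13. Its count of lower probes was 137 without control 3, 108 without DEHP 1, 69 without DEHP 2, 163 without DEHP 3 and 824 without control 2. The 5 piRNAs with the highest signal, DQ747123, DQ754272, DQ755301, DQ748751 and DQ614617, changed by -0.67, -0.48, -0.51, -0.58 and -0.53, and none passed (adjusted p from 0.105 to 0.195). Before centring and on the linear scale, DQ747123, the highest, had a signal of 226969 ± 19985 in controls and 169694 ± 7539 in DEHP testis (SD, n = 3). The change of -0.67 is of centred values and cannot be read from these signals.

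Some probes were detected in one group only. On all 3 DEHP arrays and on no control array, 389 probes were well above background, and 128 of them passed the test. On all 3 control arrays and on no DEHP array there were 7, all of which passed. These probes were selected for a separation of the groups on the arrays that the test used, so passing adds no support. Each such probe has only a bound on its fold change, the mean of the bright group over the higher of the detection floor and the dim probe's own signal. This bound was at least 2-fold for 1 of the 389 and for 6 of the 7. For some of the 389 it lay below 1, down to 0.945, and shows no increase. DQ615305 was at least 2.53-fold higher in DEHP testis (adjusted p = 0.0142), DQ621649 at least 1.97-fold (adjusted p = 0.0597) and DQ763405 at least 1.94-fold (adjusted p = 0.0443). DQ759395 was at least 3.38-fold lower in DEHP testis (adjusted p = 0.00617), DQ607852 at least 2.91-fold lower and DQ612194 at least 2.41-fold lower. The count of 389 was 1396 without control 2 and 686 without DEHP 1. The count of 7 was 244 without control 1, 13 without control 2, 12 without DEHP 1, 11 without DEHP 2 and 19 without DEHP 3. Leaving out an array removes a condition, so these counts could not fall.

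Of 56 mRNA probes tested, 24 rose and 2 fell in DEHP testis, with a median change of 0.44. The following examples were chosen after their values were seen. Pdcd10, a gene of programmed cell death and vessel integrity, rose by 0.98 with a standard error of 0.19 (adjusted p = 0.0164). Napepld, an enzyme of anandamide synthesis, rose by 0.95, Enpp1, which makes pyrophosphate, by 0.94 and the RNA-binding protein gene Mex3c by 0.84. The adaptors of Nedd4-family ubiquitin ligases Ndfip1 and Ndfip2 rose by 0.80 and 0.81, the translation factor Eif4b by 0.73 and the exon junction gene Magoh by 0.67. All 3 probes of the MHC class I light chain B2m rose, by 0.62 to 0.78. Of the 3 probes of Gapdh, a glycolytic enzyme, 2 rose by 0.65 and 0.62, and the third had 0.27 (adjusted p = 0.239). The lactate dehydrogenase gene Ldha rose by 0.91 on the catalogue probe and fell by 0.89 on 1 of 3 custom probes; the other 2 custom probes had 0.31 and 0.19 and did not pass. Gusb, a lysosomal enzyme, fell by 0.65 on 1 probe. Of 10 genes with several tested probes, 4 had probes of opposite sign. Among 25 probes from the manufacturer's catalogue 16 rose and 0 fell, with a median of 0.74; 21 of them had an unadjusted p below 0.05. Among 31 custom probes 8 rose and 2 fell, with a median of 0.27. The median of all mRNA probes was above 0 under every normalization tried, from 0.23 with median centring to 0.69 without centring. With median centring 5 mRNA probes rose and 5 fell, and the median of the custom probes was 0.06. The excess of rising over falling calls was thus not kept there. Of mRNA probes, 11 rose without DEHP 3 and 16 without centring, and 0 fell in either. The number of mRNA probes that rose was 1 without control 3, 1 without DEHP 1 and 0 without DEHP 2 (limma, 30 at an unadjusted p below 0.05). With the slide as a block it was 0 (limma; 19 at an unadjusted p below 0.05), with a median of 0.33.

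As a class, mRNA probes shifted by 0.33 on average against all other probes (limma's camera, adjusted p = 3.01e-06 with a preset correlation of 0.01 and 0.24 with an estimated one). The 16 microRNA probes shifted by -0.30 (adjusted p = 0.00149 preset and 0.259 estimated) and the piRNA probes by -0.20 (adjusted p = 0.00149 preset and 0.0404 estimated). Of the 16 microRNA probes, 11 name microRNAs of other organisms, and both that passed singly are among these 11, so the shift cannot be read as one of rat microRNAs. The piRNA probes themselves had a median change of 0.05 and a mean of 0.03, so that shift is one against the other probes. Their own median was -0.15 with median centring, -0.03 with the filter at all 6 arrays and 0.31 without centring, so its sign rests on the centring and the filter. The estimated correlation was 0.21 for mRNA, 0.38 for microRNA and 0.0016 for piRNA probes, against the preset of 0.01. The preset thus lies far below the estimate for mRNA and microRNA probes. The slide settings were run at the preset only, so their camera p-values for these classes carry the same limit. With the slide as a block the shifts were 0.21 for mRNA (adjusted p = 0.000887), -0.40 for microRNA (adjusted p = 0.000887) and -0.08 for piRNA probes (adjusted p = 0.0991). Within slide 1, also at the preset correlation, the same shifts had adjusted p of 0.00273, 0.000989 and 0.185; both settings rest on 1 control array against 3 DEHP arrays and cannot tell a group difference from a peculiarity of that array. Against the 50 piRNA probes nearest in signal level, mRNA probes lay at -0.22 ± 0.10 in controls and 0.22 ± 0.09 in DEHP testis (SD, n = 3), a difference of 0.43 (exact permutation p = 0.1, the smallest possible). The difference was 0.72 for catalogue probes and 0.20 for custom probes, each with an exact p of 0.1.

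**Figure D2:**
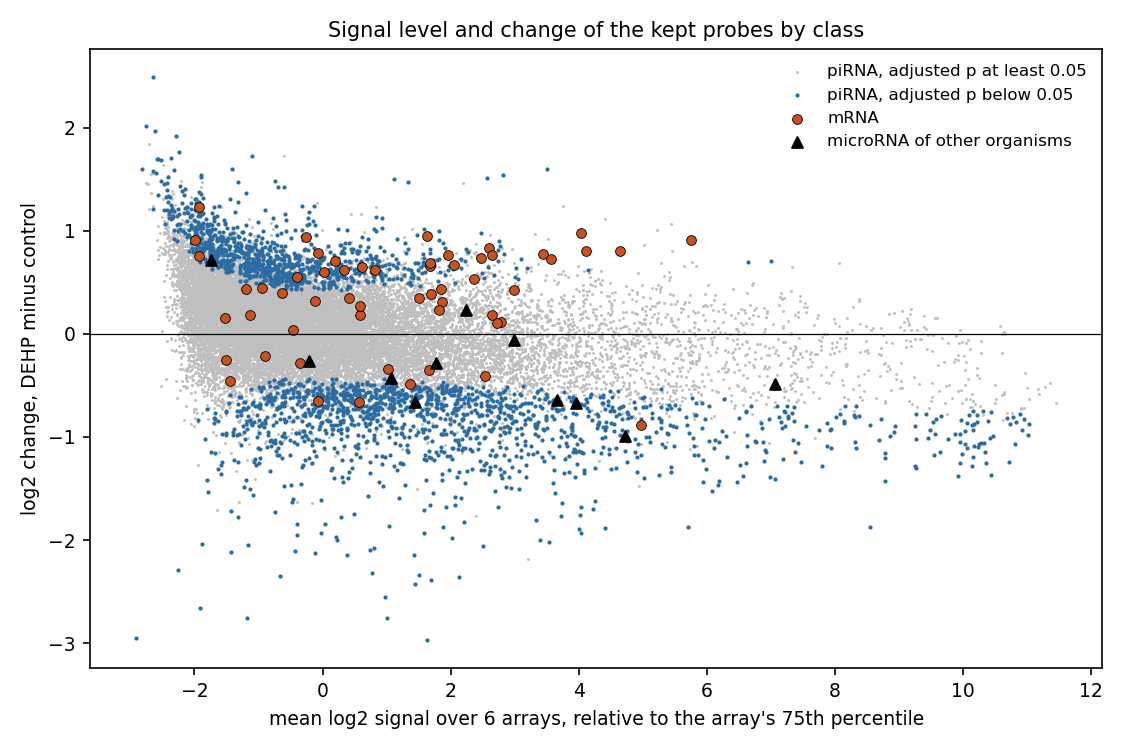
Mean log2 signal over 6 arrays relative to the 75th percentile (horizontal axis) against the log2 change, DEHP minus control (vertical axis), 1 point per kept probe: piRNA probes grey or, at an adjusted p below 0.05, blue, mRNA probes orange, and probes for microRNAs of other organisms black triangles. The median change of piRNA probes was 0.40 in the lowest of 10 bins of signal and -0.27 in the highest, or 0.13 and 0.03 after quantile normalization, the lowest bin being shaped by the detection filter, and that of mRNA probes was 0.44.

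**Figure D3:**
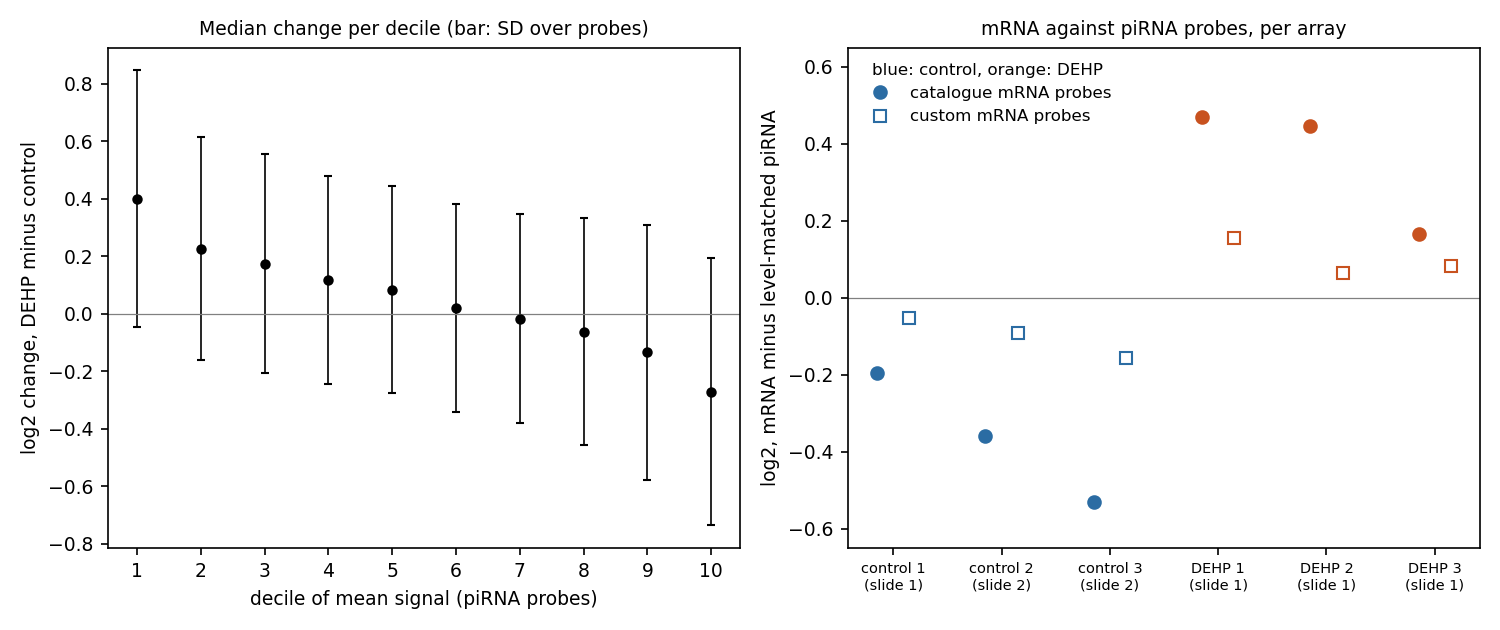
Left, the median log2 change, DEHP minus control, of piRNA probes in each of 10 bins of mean signal, with bars of 1 SD over probes; it was 0.40 in the first and -0.27 in the last, or 0.05 and 0.01 after cyclic loess, and the first is shaped by the detection filter. Right, the mean of mRNA probes minus piRNA probes of the same signal level on each array (log2), circles for catalogue and squares for custom probes, controls blue and DEHP orange; catalogue probes lay at -0.20, -0.36 and -0.53 on the control arrays and at 0.47, 0.45 and 0.17 on the DEHP arrays.

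Of 108 genes in 9 lists fixed for testis cell types, steroid synthesis, the piRNA pathway, targets of the nuclear receptor PPAR alpha, and oxidative stress and apoptosis, 1 had a probe with an assigned symbol. The 6 mRNA probes without a match and the 54 probes with other identifiers carry no symbol here and could not be searched. It was Lhcgr, the luteinizing hormone receptor of Leydig cells, whose change was 0.55 with a standard error of 0.18 (adjusted p = 0.0784). It did not pass over all probes. Adjusted over the list alone 1 of 1 measured gene was below 0.05, which with a single gene is no adjustment and is not counted as a pass. With the 75th percentile over probes detected on all arrays its adjusted p was 0.0447, and over all alternatives of this probe it ranged from 0.0297 without control 1 to 0.7 with the slide as a block. The other lists had no gene with an assigned probe and were not tested.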

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

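The tests of the slide, of the intensity-dependent response and of the probe family were chosen only after the results they bear on were seen; the counts over other splits and the test of array position were set beforehand.

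Probes named for microRNAs of viruses, nematodes, plants and planarians have no named target in rat RNA and lie outside the piRNA measurement, and the signal of some of them drew attention. Of 27 such probes, 16 were well above background on no array and 10 were well above background on all 6 arrays (37.0%, 95% exact binomial interval 19.4 to 57.6%, over probes), against 41.7% of 39727 piRNA probes. The mean signals were 9415 for ppt-miR535a, 1905 for ebv-miR-BART17-5p, 1096 for mcmv-miR-m108-2-3p, 895 for rrv-miR-rR1-5, 559 for mcmv-miR-m01-1, 337 for mcmv-miR-M87-1, 241 for mghv-miR-M1-3, 198 for ebv-miR-BART6-3p, 148 for mdv2-miR-M30 and 61.6 for cel-miR-49. The negative control spots had a median signal of 3.70 and a highest of 240.1, which lies above the mean of the last 3 of these 10. The signal of ppt-miR535a exceeded that of 99.0% of piRNA probes. Of the 11 tested probes, 2 were lower in DEHP testis (ebv-miR-BART17-5p by -0.99, adjusted p = 0.00914, and rrv-miR-rR1-5 by -0.64, adjusted p = 0.0374), and their median change was -0.43.

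The first pattern weighed is the 2471 probes that differed between DEHP and control testis, for which a treatment difference stays among the open explanations. The real grouping gave 2471 calls and the highest of the 9 other splits of the 6 arrays gave 1, so 1 of 10 splits reached the real count; 10 splits are too few for a share under 0.05. For probes past an unadjusted p of 0.05 with at least a 2-fold change, 1 of 10 splits reached the real 672, and the highest other gave 119. Every other split mixes the groups, so a difference between them, of whatever cause, enters its residual variance and lowers its count. An intensity-dependent response of the arrays as the whole cause is argued against by cyclic loess, which removes such a trend and left 1580 of the 2471 probes called, and a position effect by a correlation of 0.0182 between the changes of neighbouring spots. The slide stays open. Control 1 was the only control on the slide of the DEHP arrays. Among 2578 probes called without it, it lay at a median position of 0.3649 between the other controls (0) and the DEHP mean (1). It lay short of the DEHP mean in 95.7% of probes and nearer the controls in 66.4%. Across all kept probes it correlated with the DEHP arrays at 0.975 to 0.982, with control 2 at 0.976 and with control 3 at 0.985. With the block 7 probes passed, 1 of them among the 2471. All 2471 kept their sign, but control 1 had helped to select them, so this tests no slide effect. A slide effect is not excluded by 1 such array.

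The second pattern is the higher position of mRNA probes than of piRNA probes of the same level in DEHP testis, where a difference between treatments stays open. A response that depends on intensity alone is argued against by the difference of 0.433 at matched level, above 2 SDs of either group (SDs 0.10 and 0.09). A difference between probe families may contribute: foreign microRNA probes, which name neither a piRNA nor an mRNA of the rat, lay -0.3079 from piRNA probes of their level (SD 0.38 over 11 probes), not above them as mRNA probes did, although they could also be reading piRNAs. The slide stays open, since the lowest DEHP array exceeded control 1 on the same slide by 0.2355 and only 1 control lies there.

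For the class shifts, 2 of 10 splits gave an mRNA shift as large as the real one by camera, the other being control 1 with DEHP 1 and DEHP 2 against the rest, which parts all but 1 array by slide (-log10 of camera's unadjusted p 6.00 for the real split and 6.46 for the other). For piRNA probes 3 of 10 did (2.87 and, at most, 5.50), the larger ones again close to the split by slide, and for microRNA probes 3 of 10 (2.83 and, at most, 4.10). A count of 10 splits allows no share under 0.1.

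The count of probes detected in one group only, 389 in DEHP and 7 in control testis, stands beside 518 for the split of control 1, control 3 and DEHP 1 against the rest. A count of this size thus also arose in a split that mixes the groups.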

How the results depend on the processing

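Cyclic loess, slide 1 alone, the slide and other scalings in the class tests, and arrays left out of the detection counts were chosen after seeing the data. The sign of all 2471 calls was kept wherever they were tested, except 3 of them under normexp with quantile normalization. Every setting reused arrays that had selected these probes, so a kept sign was largely set by the selection. The count of 2471 was 568 without centring, 1598 with normexp and 75th percentile centring, 7 with the slide as a block and 4000 with array weights, and ranged from 275 to 4514 when 1 array was left out. The 1026 higher probes were 316 without centring, 2501 with the percentile over probes detected on all 6 arrays, 298 with median centring, 500 with normexp and percentile centring, 662 with the filter at all 6 arrays, 0 with the slide as a block (limma; 2092 at an unadjusted p below 0.05) and 1895 with array weights, with a range of 25 to 2134 when 1 array was left out. The 1445 lower probes were 252 without centring, 2840 with median centring and 7 with the slide as a block, with a range of 250 to 2380. Whether the replicate numbers pair the samples cannot be told from so few arrays. Same-numbered arrays deviated from their group means at r = 0.13, 0.46 and 0.08. The DEHP array of the same number was the closest for controls 1 and 2, and DEHP 1 was the closest for control 3. With the replicate block 4465 probes were called, 2053 higher and 2412 lower. The 672 probes past the unadjusted threshold were 1046 without centring, 114 with normexp and quantile normalization, 158 with normexp and percentile centring, 1748 without a filter, 424 with the filter at all 6 arrays, 432 after cyclic loess and 3429 at 1.5-fold. The 389 probes detected in DEHP only were 826 at 2 of 3 arrays and 394 to 1396 with 1 array left out. The 7 in control only were 253 and 10 to 244. Each of these settings loosens the rule, so the counts could not fall. Among the classes, camera with an estimated correlation left mRNA (0.33, adjusted p = 0.24) and microRNA probes (-0.30, adjusted p = 0.259) short of the threshold, as did fry for microRNA probes (mean -0.27, adjusted p = 0.051); fry, which tests a class on its own, gave the piRNA probes a mean of 0.0343 (adjusted p = 0.0142), of the opposite sign, but centring sets that mean and nothing is read from it. With the slide as a block or within slide 1 their shift was -0.0805 and did not pass. The causes were not tested, apart from the fewer probes or arrays in a setting.

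Of 660 values of the 30 named probes under the alternatives, 556 kept their direction and side of the threshold, 74 kept the direction and lost the call, 16 gained a call and 14 changed sign. The probes named for large changes had been selected for passing on these same arrays, so their kept direction was largely set by the selection. The probes named for their bounds are not among the 30. All sign changes were in piRNAs of highest signal that had not passed. Under quantile normalization, the authors' value table and cyclic loess, DQ754272 had 0.0929, 0.086 and 0.1418, DQ755301 0.0615, 0.061 and 0.102, DQ748751 0.0546, 0.0473 and 0.0313, and DQ614617 0.1304, 0.1181 and 0.0755; under normexp with quantile normalization DQ755301 had 0.1326 and DQ614617 0.077. Quantile normalization and cyclic loess bring bright probes towards 0 by construction, and the authors' columns share 1 maximum. The difference in detected probes and in the 75th percentile kept its direction under every alternative, with an exact p of at least 0.1, and the planned cluster alternative was not run because no positions were used. Signal over background limits the dimmest probes: 13875 of 39727 piRNA probes (34.9%) were well above background on no array.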

Other observations

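The tests here were set before their own results were seen, after the values that prompted them had been.

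Probes of the array with neither a piRNA, an mRNA nor a microRNA name (expressed sequence tags and other accessions) were not tested as a class. Of 30 tested singly, 10 were higher and 2 lower in DEHP testis and 18 did not pass, with a median change of 0.40. The median was 0.19 with median centring and 0.18 with the slide as a block. It was -0.16 without a filter, where all 54 enter.

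The 5 piRNA probes with the largest increases among those that passed and were well above background on all 6 arrays, DQ625003, DQ760294, DQ758000, DQ743578 and DQ612411, have identifiers that do not adjoin, and their deviations from the group means over the 6 arrays were nearly alike. The lowest pairwise correlation of these profiles was 0.9297. The 5 were singled out for this likeness, so the value is a description and tests no cause. Of the 166 piRNA probes called at least 2-fold higher, 6 correlated above 0.95 with the mean profile of the 5, which are among the 6. Whether these probes read one group of related RNAs stays open, as do cross-hybridisation and shared regulation.

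piRNA probes with consecutive identifiers changed alike more than distant ones. Over 8938 consecutive pairs, across probes that are not independent replicates, the correlation of the log2 change was 0.16 (permutation p = 0.001, the smallest 1000 shuffles allow; highest shuffle 0.04), against 0.02 for probes 10 places apart. Position on the array is argued against, since the median distance between spots of consecutive identifiers was 1.0085 times that of random spots. A shared signal level is argued against too: with the trend of change on level removed the correlation was 0.1531. That consecutive identifiers may come from one locus or sequence family is a hypothesis that was not tested.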
